A study of Amphiprion ocellaris with 30 samples.

How the data were processed

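RNA was measured in 30 libraries made from entire wild-type larvae of the clownfish Amphiprion ocellaris, collected 5 days after the start of treatment. The larvae had been kept in beakers of sea water at 27°C with one of 3 treatments. These were the solvent DMSO (dimethyl sulfoxide) at 0.0001%, SR9243 at 1e-07 M, or T3 at 1e-07 M. No DMSO concentration was recorded here for the SR9243 and T3 libraries, so whether they received the solvent is not known. Groups and library numbers (1 to 10 in each group) were taken from the sample titles. The titles of the T3 libraries also carry the tag IOP, which the labels do not explain, and the treatment label of these libraries names T3 alone. The labels do not state whether each library is 1 larva, which beaker or clutch it came from, or when it was sampled. P-values therefore measure the spread between these libraries, and larvae that shared a beaker would not be independent.

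Libraries were stranded, poly(A)-selected and sequenced as read pairs of 150 bases, per the labels' protocols. FastQC 0.11.8 and kallisto 0.46.1 are named in the submitters' processing notes. The annotation release, the genome build and the tool that made the final values are not given in the sources used here. The authors deposited 1 table of variance-stabilised normalised counts for 22816 Ensembl gene IDs, on a scale close to log2 at high values and compressed at low values. These log2-scale values ran from 2.88 to 18.7. The lowest value was shared by all libraries and was read here as a count of 0. Total counts per library are not in this table, so the depth is unknown and no interval or detection floor based on depth was computed. Low values did not fall on a few steps per library: in DMSO library 1, 1294 of the 1321 values between the lowest value and 4 were distinct. As a stand-in for detection, the number of genes listed at 0 was counted per library. All 30 columns were matched to samples, and 0 columns were left without one.

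The table names genes by Ensembl ID only. The reference gene table used here (28286 genes) held 0 Ensembl IDs, so 0 of the 22816 IDs could be given a symbol, and no coordinates are printed. The 27 gene lists and the symbol-based rule for named genes, fixed before the data were examined, could therefore not be applied. In their place the 2 largest differences in each direction among called genes are given by ID for each comparison, the most that is printed for unnamed IDs. The other gene groups are classes defined by the tests themselves.

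Genes above the lowest value in at least 10 of the 30 libraries were tested, which removed 201 genes and left 22615. One linear model per gene was fitted over the 3 groups with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend), with the treatment as the only factor. Contrasts were SR9243 against DMSO, T3 against DMSO and SR9243 against T3. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. A gene past it is called below. No count model was used, because the values are not counts. The model was tested on simulated data, with 50 genes changed at each of several sizes among 22615. At a log2 size of 0.5, it recovered 62% of the changed genes for SR9243 against DMSO and 64% for T3 against DMSO. At a size of 1 the recovered shares were 92% and 96%, and false calls among the unchanged genes numbered 4 and 8. The simulated values were independent and normal, with the same SD of a gene in every group. The real libraries had a wider DMSO group and the sets described further on. These numbers are therefore not the error rate of the real comparisons.

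Each library was also placed on a T3 axis, the line through all tested genes from the DMSO mean (0) to the T3 mean (1). A library's own values were left out of the means it was projected on. Group differences in single values per library were tested with 100000 permutations of the labels, two-sided, with Benjamini-Hochberg adjustment over 12 tests. Agreement between the SR9243 and T3 responses was set against 100 simulated triplets of unchanged groups, drawn from the libraries' deviations from their group means. It was also recomputed with the 10 DMSO libraries split 5 and 5 between the comparisons (20 random splits).

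Same-numbered libraries of different groups were checked for shared deviations. The correlation was above 0.1 in 7 of 30 pairs and as low as -0.28, so no pairing by number was seen. Same-numbered SR9243 and T3 libraries fall in opposite sets, described further on, which pulls their correlation down. A weaker pairing is therefore not excluded. No library was counted as a duplicate: the highest correlation between 2 libraries of a group was 0.987. Alternatives tried were other filters, scalings, variance models, library weights, a rank test, a minimum size, a replicate block and leaving out each library. The split of libraries 1 to 5 against 6 to 10, the set terms and the removal of DMSO libraries 4 and 7 were added after the data were seen. The sets were found in the data, not in the labels, and DMSO libraries were divided between them by the order of their score on genes chosen without DMSO. Figures were drawn with matplotlib 3.10.9.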

Results

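Gene expression was measured by RNA sequencing in clownfish larvae exposed for 5 days to the solvent DMSO, to SR9243 or to T3, with 10 libraries in each group. SR9243 is a synthetic ligand described in the series title as an antagonist of LXR, the liver X receptor, a nuclear receptor that controls cholesterol and lipid metabolism. T3 (triiodothyronine) is the active thyroid hormone, which drives metamorphosis in fish and amphibians. Values are the authors' variance-stabilised counts, and differences are given on that log2-like scale with their standard error (SE). Of 22816 genes, 20564 were above the lowest value in all 30 libraries. The number of genes listed at 0 was 626 ± 41.3 (SD, n = 10) in DMSO, 649 ± 40.8 in SR9243 and 657 ± 35.1 in T3 libraries. It did not pass the test in any of the 3 comparisons (permutation test, adjusted p = 0.271, 0.116 and 0.636 for SR9243 against DMSO, T3 against DMSO and SR9243 against T3). The median value of a library was 6.85 in DMSO, 6.88 in SR9243 and 6.91 in T3 on average. It differed in these 3 comparisons (permutation test, adjusted p = 0.00022, 3e-05 and 0.000144), which bears on the counts of higher and lower genes below. With the authors' scaling, the median gene differed by -0.0075 for SR9243 against DMSO, -0.0149 for T3 against DMSO and 0.0034 for SR9243 against T3. Setting library medians equal lowers every difference from DMSO by 0.0292 for SR9243 and 0.0558 for T3, and raises SR9243 against T3. It thus moves the median gene further from 0, which favours lower calls against DMSO and higher calls for SR9243 against T3.

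T3 against DMSO asks which genes differed in the libraries labelled T3. Their titles also carry the unexplained tag IOP, so if it marks a further treatment, the values given for T3 throughout are those of a combined one. T3 changed 11430 of 22615 tested genes (50.5%), of which 5601 rose and 5829 fell. This balance held with the authors' scaling: with library medians set equal 4853 rose and 6965 fell, and with quantile normalisation 5099 rose and 6535 fell. The median size of a called difference was 0.50, so most changes were small. A difference of at least 1 was found for 1114 genes that rose and 489 that fell, and a difference of at least 2 for 198 that rose and 93 that fell. Calls were found at every expression level, in 40.1% of the genes in the lowest tercile of mean level, 52.2% in the middle tercile and 59.3% in the highest.

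The 2 largest increases with T3 were in ENSAOCG00000015745 and ENSAOCG00000000554. ENSAOCG00000015745 rose by 8.04 (SE 0.68, limma adjusted p = 2.5e-11), from 4.97 ± 2.78 (SD, n = 10) in DMSO to 13.0 ± 0.27 with T3. It was listed at 0 in 5 of the 10 DMSO libraries and lay between 3.41 and 9.45 in the others. ENSAOCG00000000554 rose from 4.32 ± 0.69 to 12.2 ± 0.62, a difference of 7.89 (SE 0.28, limma adjusted p = 5.8e-20). The 2 largest decreases were in ENSAOCG00000011699 and ENSAOCG00000003252. ENSAOCG00000011699 went from 11.7 ± 1.07 to 3.75 ± 0.42, a difference of -7.95 (SE 0.35, limma adjusted p = 6.5e-18). ENSAOCG00000003252 went from 12.1 ± 0.45 to 4.29 ± 0.34, a difference of -7.78 (SE 0.17, limma adjusted p = 8.1e-26). The 10 T3 and 10 DMSO libraries did not overlap at all for 2722 genes, 1601 higher and 1121 lower with T3, where chance gives 0.00108% of genes. No gene was listed at 0 in all libraries of one of these groups and above it in all of the other. With means over libraries 1 to 5 and 6 to 10 as the units (2 per group), 7855 genes were called for T3, of which 7773 were also called with single libraries. Both fits have the same group means, so the direction of a difference cannot change between them.

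SR9243 against DMSO asks which genes responded to the LXR ligand. SR9243 changed 6568 genes (29%), of which 3385 rose and 3183 fell, with a median called size of 0.43. A difference of at least 1 was found for 298 genes that rose and 152 that fell, and a difference of at least 2 for 52 and 18. The share of genes called was 16.9% in the lowest tercile of mean level, 31.0% in the middle and 39.2% in the highest. The SR9243 and DMSO libraries did not overlap for 382 genes, 269 higher and 113 lower with SR9243. The order of higher and lower calls turned with the scaling. With library medians set equal, 2990 rose and 3781 fell, and with quantile normalisation 3196 rose and 3551 fell. Equal medians lower every difference from DMSO, as given above, so they favour lower calls.

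The largest increase with SR9243 was in ENSAOCG00000015745, the gene that also led the T3 response. It reached 10.8 ± 0.58 (SD, n = 10), 5.79 above DMSO (SE 0.68, limma adjusted p = 2.6e-07). ENSAOCG00000013773 followed, rising from 4.29 ± 1.30 to 8.0 ± 0.77, by 3.71 (SE 0.38, limma adjusted p = 2.3e-08), and it stood at 9.55 ± 0.46 with T3. The 2 largest decreases were in ENSAOCG00000024738, with a difference of -4.94 (SE 0.45, limma adjusted p = 4.1e-09), and in ENSAOCG00000013714, with -4.71 (SE 0.45, limma adjusted p = 7.7e-09). ENSAOCG00000024738 went from 9.05 ± 1.34 in DMSO to 4.11 ± 1.23 with SR9243 and 3.29 ± 0.45 with T3. ENSAOCG00000013714 went from 11.7 ± 1.52 to 6.95 ± 1.01 with SR9243 and 5.58 ± 0.43 with T3. SR9243 library 3 stood apart for both, at 7.36 and 9.63. All 4 of these genes moved the same way under both treatments. The count of SR9243 calls depended on the unit of replication. With means of 5 libraries as the units it was 2630, of which 2580 were also called with single libraries.

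The SR9243 and T3 responses were then set side by side. Of the SR9243 calls, 4832 genes (73.6%) were also called with T3 in the same direction, 2690 higher and 2142 lower. The order of higher and lower turned with the scaling, to 2332 and 2730 with library medians set equal and to 2477 and 2587 with quantile normalisation. Independent lists of these sizes would share 838 higher and 820 lower genes. Opposite calls numbered 74, against 1661 for independent lists. Across genes, which are not independent replicates, the correlation of the 2 sets of differences was 0.75 and their covariance 0.172. The comparisons share the DMSO libraries, and simulated unchanged groups gave a median correlation of 0.52 (-0.080 to 0.854), a range that includes the observed one, a median covariance of 0.0102 (highest 0.0513) and a median of 0 shared calls. With the DMSO libraries split between the comparisons, the covariance had a median of 0.16 (0.128 to 0.171 over 20 splits) and the shared genes a median of 3122, with 1044 for independent lists. With means of 5 libraries as the units, 2132 genes were shared, 1356 higher and 776 lower.

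**Figure D1:**
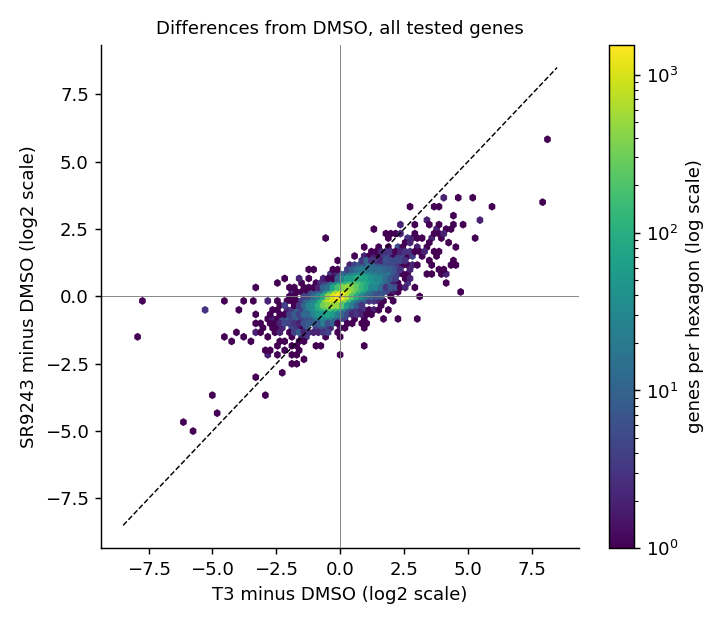
Difference from DMSO with SR9243 (vertical axis) against T3 (horizontal axis), on the log2-like scale, for the 22615 tested genes. Colour gives the number of genes per hexagon on a log scale, and the dashed line marks equal differences. Most genes far from 0 lie nearer to the horizontal axis than the dashed line does, with 2690 genes called higher and 2142 called lower in both.

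Shared genes moved further with T3. Among the shared higher genes the median difference was 0.50 with SR9243 and 0.72 with T3, and among the shared lower genes -0.41 and -0.57. The direct test between treatments called a larger change with T3 for 1815 of the 4832 shared genes (37.6%), a larger change with SR9243 for 75, and neither for 2942. Genes chosen by the size of a change under one treatment favour that treatment in such a comparison, so both choices are given. Of the 198 genes that rose by at least 2 with T3, 167 were also called higher with SR9243, 30 were not called and 1 was called lower; the median was 2.55 with T3 and 1.36 with SR9243. Of the 93 genes that fell by at least 2 with T3, 68 were also called lower with SR9243, 24 were not called and 1 was called higher, with medians of -2.42 and -0.92. In the other direction, 51 of the 52 genes that rose by at least 2 with SR9243 and 17 of the 18 that fell so far were called the same way with T3. The genes chosen by SR9243 had medians of 2.49 with SR9243 and 3.64 with T3 among those that rose, and of -2.40 and -2.31 among those that fell.

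On the T3 axis, where the DMSO mean is 0 and the T3 mean 1, SR9243 libraries lay at 0.469 ± 0.0796 (SD, n = 10). DMSO libraries lay at 0.0414 ± 0.133 and T3 libraries at 0.975 ± 0.0403. The lowest SR9243 library (0.296) was above the highest DMSO library (0.242), and the highest SR9243 library (0.589) was below the lowest T3 library (0.913). The distance between DMSO and T3 libraries is set by how the axis is built, so its p is not given. SR9243 libraries, which do not enter the axis, differed from DMSO and from T3 libraries with a permutation p of 1e-05 each, the smallest that 100000 permutations can give (adjusted p = 3e-05). Over genes called with T3, the slope of the SR9243 differences on the T3 differences was 0.47, and 0.44 (0.29 to 0.52) with split DMSO libraries. Because these full ranges did not overlap, the same order within each of the 2 sets of libraries described further on follows from them. The axis was not rebuilt within the sets, so the values per set are no further test. In the first set the highest DMSO library lay at 0.125, SR9243 at 0.431 to 0.589 and the lowest T3 library at 0.952; in the second set the values were 0.242, 0.296 to 0.514 and 0.913.

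**Figure D2:**
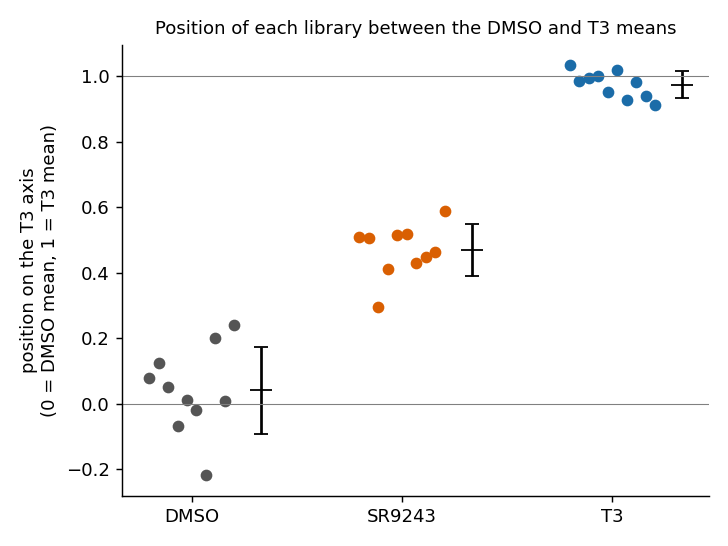
Position of each library on the T3 axis (vertical axis, no unit; 0 is the DMSO mean and 1 the T3 mean), by group. Points are libraries in the order of their numbers, and bars show the group mean and SD (n = 10). SR9243 libraries lie between 0.296 and 0.589, apart from the DMSO and T3 libraries.

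SR9243 against T3 asks where the 2 treatments differed from each other. The DMSO libraries cancel in this difference, but they enter the estimate of spread that the 3 groups share. The contrast called 7841 genes (34.7%), 3877 higher and 3964 lower with SR9243, with a median size of 0.41. With only these 2 groups fitted, the count was 9198. With library medians set equal 4381 were higher and 3524 lower, and with quantile normalisation 4016 and 3524. With means of 5 libraries as the units the count was 3150, 1293 higher and 1857 lower, of which 3090 were also called with single libraries. A difference of at least 1 was found for 216 genes higher with SR9243 and 393 genes lower. Of the 4 genes with the largest differences, 3 were also among the largest T3 changes. ENSAOCG00000003252 stood at 11.8 ± 0.44 (SD, n = 10) with SR9243, 7.53 above T3 (SE 0.17, limma adjusted p = 2.2e-25). Against DMSO its SR9243 difference was -0.24 (SE 0.17, limma adjusted p = 0.311). ENSAOCG00000011699 was 6.55 higher with SR9243 than with T3 (SE 0.35, limma adjusted p = 3.5e-15), and it also fell against DMSO, by 1.41 (limma adjusted p = 0.00278), with SR9243 library 3 apart from its group at 12.5. ENSAOCG00000020520 was lower with SR9243, with a difference from T3 of -4.61 (SE 0.19, limma adjusted p = 6.1e-18), with means of 5.88 ± 0.65 in DMSO, 5.97 ± 0.34 in SR9243 and 10.6 ± 0.27 in T3 libraries; DMSO library 7 was apart at 4.39. ENSAOCG00000000554, at 7.82 ± 0.70 with SR9243, differed from T3 by -4.38 (SE 0.28, limma adjusted p = 1.9e-13) and was 3.51 above DMSO (limma adjusted p = 6.3e-10).

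Genes were also grouped by requiring both a call against DMSO and a call in the direct test. T3-distinct genes, called with T3, not called with SR9243 and called between the treatments, numbered 4098, of which 1787 rose and 2311 fell. Their median T3 difference was 0.53 among those that rose and -0.46 among those that fell. SR9243-distinct genes, defined in the same way, numbered 771, with 285 that rose (median 0.42) and 486 that fell (median -0.39). A size of 1 was reached by 4 of those that rose and 13 of those that fell. A further 2426 genes called with T3 alone and 891 called with SR9243 alone were not called in the direct test. They are in neither distinct class. The 74 genes with opposite calls were 40 higher with SR9243 and lower with T3, and 34 the reverse. All were called in the direct test, which had to follow: the contrasts share their SE, and opposite differences add up between the treatments. This direct call is no further support.

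**Figure D3:**
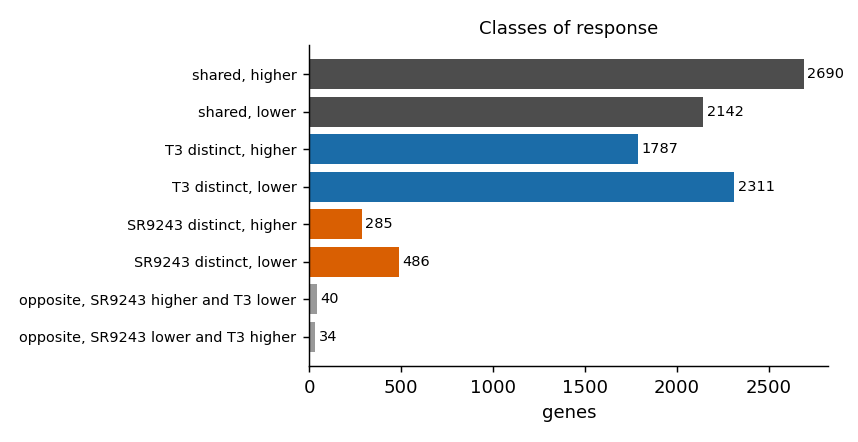
Number of genes (horizontal axis) in the shared, distinct and opposite classes of response. Genes called with T3 alone (2426) or SR9243 alone (891), and not between the treatments, are not drawn. Shared genes were called against DMSO in the same direction with both treatments; distinct genes were called with one treatment and between the treatments but not with the other. The shared classes hold 2690 and 2142 genes, and the SR9243-distinct classes 285 and 486.

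Libraries of one treatment were not all alike. Within SR9243, libraries 6 to 10 differed from libraries 1 to 5 in 1129 genes, and within T3 in 1012 genes (limma, 5 against 5). Within DMSO the same division called 0 genes, with 671 at an unadjusted p below 0.05. The genes called in both treatments numbered 502, against 50.5 for independent lists, and 499 of them differed in opposite senses. SR9243 libraries 6 to 10 thus shared a state with T3 libraries 1 to 5, termed the first set here. In this set 483 of the 499 genes were higher, by a median of 0.75, and 16 were lower. The genes were chosen for differing between these libraries, so the size of the difference is raised by that choice. On a score from 0 (second set) to 1 (first set) built on these genes without DMSO, DMSO libraries 1 to 4 lay at 0.35 to 0.752 and DMSO libraries 5 to 10 at -0.133 to 0.219. No label gives DMSO libraries a set; for the repeats within sets, libraries 1 to 4 were put with the first and 5 to 10 with the second, after the score was seen. DMSO libraries 1 to 3 (0.35 to 0.441) were nearer to the second set than to the first, so the first set's DMSO libraries do not match its treated ones.

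**Figure D4:**
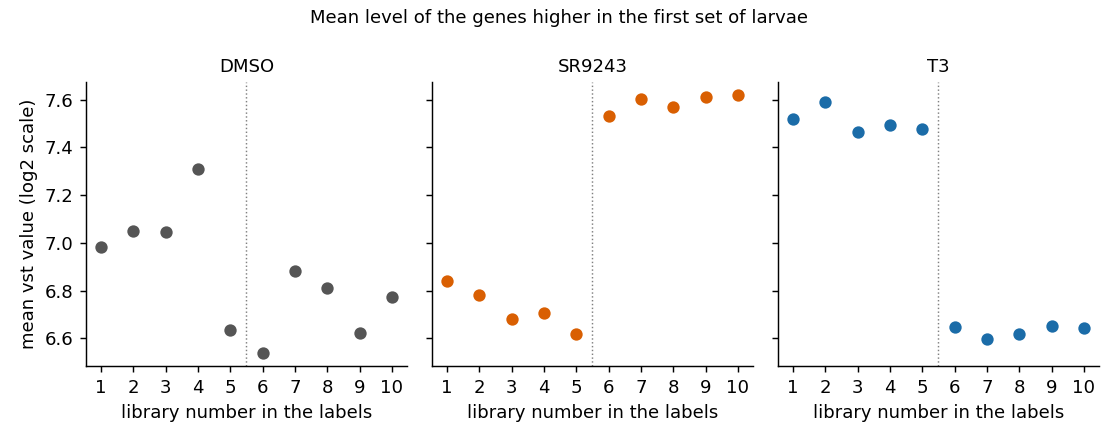
Mean level (vertical axis, variance-stabilised log2-like scale; it does not start at 0) of the 483 genes higher in the first set, for each library by its number in the labels, in 3 panels by group. The dotted line parts libraries 1 to 5 from 6 to 10. The level averaged 7.55 in SR9243 libraries 6 to 10 and T3 libraries 1 to 5, and 6.68 in the other libraries of these treatments. The genes were chosen for this difference, so the gap follows from the choice. DMSO libraries did not enter it.

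The comparisons were repeated within the sets, which hold fewer libraries, with the limit just given for the first set. In the first set, with DMSO libraries 1 to 4, 3066 genes were called for SR9243, 7924 for T3, 3359 between the treatments and 2576 as shared. In the second set, with DMSO libraries 5 to 10, the counts were 3648, 8150, 5363 and 2169. The covariance of the SR9243 and T3 differences was 0.199 in the first set and 0.164 in the second. With the set as a term over all libraries, 6813 genes were called for SR9243, 11627 for T3, 8251 between the treatments and 4984 as shared.

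DMSO libraries were more spread out than the treated ones. The median SD of a gene was 0.287 among DMSO, 0.230 among SR9243 and 0.216 among T3 libraries. The root-mean-square distance of a library to the mean of the others of its group was 0.39 ± 0.124 (SD, n = 10) in DMSO, 0.314 ± 0.0298 in SR9243 and 0.304 ± 0.0226 in T3 (permutation test against DMSO, adjusted p = 0.0292 and 0.00754). DMSO libraries 4 and 7, one in each set, had the largest distances. Without them, and with the other groups whole, the median SD was 0.229 and the distance 0.331 ± 0.0308 (SD, n = 8), and neither comparison passed (exact permutation test, p = 0.253 for SR9243 and 0.0538 for T3). Leaving the 2 farthest libraries out of DMSO alone lowers its spread by construction. With the 2 farthest left out of every group, the distance was 0.331 in DMSO, 0.301 in SR9243 and 0.301 in T3, and both comparisons passed (exact permutation test, n = 8, adjusted p = 0.0396 and 0.0392). Leaving DMSO libraries 4 and 7 out raised the calls to 7514 for SR9243, 11667 for T3, 9152 between the treatments and 5260 shared.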

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

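Among the tests below, the divisions of each group by library number, the check for exchanged labels, the correlation of these divisions between treatments and the removal of the farthest libraries were chosen after the result had been seen. The covariate for genes listed at 0 and the comparison of DMSO libraries 4 and 7 with the T3 minus SR9243 difference were planned before their results were seen.

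The difference between libraries 1 to 5 and 6 to 10 was not the same in SR9243 and T3: an interaction term called 2088 genes, and the highest of the other divisions tried called 43. The division by number gave 1129 genes within SR9243 (highest other division 4) and 1012 within T3 (highest other 27). It was the only division of the 100 tried to reach its count in each of these 3 tests (1 of 100). Because this division was chosen after the libraries had been seen to differ, its rank does not exclude chance. Within DMSO it called 0 genes with limma (671 at an unadjusted p below 0.05). Any division reaches a count of 0, so a rank among divisions cannot be read for DMSO.

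Depth itself is unknown, so only its stand-in, the number of genes listed at 0, was tested. In SR9243 its mean was 664 in libraries 1 to 5 and 633 in 6 to 10 (exact permutation p = 0.254). In T3 the means were 654 and 659 (exact permutation p = 0.817). With it as a covariate, 55.4% of the genes within SR9243 stayed called, and more within T3 (959 of 1012). This argues against the stand-in as the whole cause, but does not decide depth. An exchange of SR9243 and T3 labels is argued against because the lowest T3 library lay 0.324 above the highest SR9243 library on the T3 axis. A shared beaker, clutch or handling batch stays open. The differences by library number correlated at -0.42 between the treatments across genes, which such a batch might give, but the labels name none, so it cannot be told apart from a difference in the biology of the larvae. If libraries 1 to 5 and 6 to 10 came from separate beakers, the number of independent units would be below 10 per group.

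DMSO library 7 stood apart from the other DMSO libraries, at a distance of 0.72 from their mean against 0.437 for the next one, DMSO library 4. Whether these 2 libraries alone make the DMSO group wider stays open. With the 2 farthest libraries left out of every group, the median SD in DMSO was 110% of that in SR9243, and the distances still differed (0.331 against 0.301, exact permutation test, n = 8, adjusted p = 0.0396). A candidate explanation, that both were further back on the way from the SR9243 to the T3 state, was not decided. Their deviations correlated with the T3 minus SR9243 difference across genes at -0.16 (library 4) and -0.21 (library 7), while the other DMSO libraries spanned -0.24 to 0.195.

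Other single libraries were far from their group. ENSAOCG00000020520 was at 4.39 in DMSO library 7, and the next lowest DMSO value was 5.59. SR9243 library 3 was highest in its group for 3 of the genes that the treatments lowered most: ENSAOCG00000024738 at 7.36 (next 4.55), ENSAOCG00000013714 at 9.63 (next 7.20) and ENSAOCG00000011699 at 12.5 (next 10.9). T3 library 2 had the largest distance in its group, 0.363 against 0.309. Of 37 groups of values tested, 6 had such a library, where chance gives about 1 in 20.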

How the results depend on the processing

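The counts of called genes were 6568 for SR9243 against DMSO, 11430 for T3 against DMSO, 7841 between the treatments and 4832 shared. Under other filters, scalings, variance models, library weights, fits of 2 groups, a rank test and a replicate block, each stayed within 1.5 times these values. Within that range, fits of 2 groups gave 5546 for SR9243 against DMSO, 10939 for T3 against DMSO and 9198 between the treatments. Library weights gave 7964, 12037 and 10090. The shared count was not computed under the weights, the fits of 2 groups and the rank test. Leaving out each library in turn gave 5852 to 7240, 11046 to 11635, 6908 to 8868 and 4332 to 5150, with the highest of each without DMSO library 7. With the replicate number as a block the counts were 6197, 11131, 7453 and 4609. No pairing by number was seen, and 4 of 30 libraries correlated best with their own number. A minimum size of 1, which keeps fewer genes by construction, left 450, 1603, 609 and 357. The remaining alternatives were added after the data were seen. Over all 30 libraries, the set as a term gave 6813, 11627, 8251 and 4984, and the set score as a covariate 6213, 11433, 8313 and 4545. The others use fewer libraries or units. The first set alone gave 3066 for SR9243, 3359 between the treatments and 2576 shared, and the second set alone 3648 for SR9243 and 2169 shared. Means of 5 libraries as 6 units gave 2630, 3150 and 2132, and DMSO libraries split between the comparisons gave 3122 shared genes. All 492 values of the 12 gene and comparison pairs named by ID kept their direction and stayed past the threshold under the alternatives run on them. These pairs were chosen for the largest differences, so this does not show how smaller called differences hold. The gene list tests and their alternatives were not run, because no gene ID could be given a symbol. Shared genes were more often higher with the authors' scaling (2690 against 2142). They were more often lower with library medians set equal (2332 against 2730) or quantile normalisation (2477 against 2587). Equal medians lower every difference from DMSO and so favour lower calls. Low values are compressed by the variance stabilisation, which limits the size of differences for weakly expressed genes.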

Other observations

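Of the tests in this part, the covariances within the 2 sets of libraries, the removal of DMSO libraries 4 and 7, the DMSO libraries split between the comparisons and the places relative to uncalled genes or without DMSO were chosen after the data or related results had been seen. The within-set test first used the correlation and was changed to the covariance, because simulated unchanged groups gave correlations of up to 0.854.

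In some of the named genes, single DMSO libraries lay towards the treated ones. ENSAOCG00000015745 was at 9.45 and 9.11 in DMSO libraries 8 and 10, while 5 of the 10 DMSO libraries listed it at 0. The same 2 libraries had the lowest DMSO values of ENSAOCG00000013714 (8.40 and 9.44) and ENSAOCG00000024738 (6.11 and 7.31). ENSAOCG00000000554, which both treatments raised, had its highest DMSO values in them too (5.72 and 4.87, against a mean of 4.32). The other 4 named genes did not follow this in both libraries. ENSAOCG00000013773 was at 6.66 in DMSO library 8 but 3.59 in library 10, below the DMSO mean of 4.29. ENSAOCG00000011699 was lowest in DMSO libraries 2 and 7 (10.04 and 10.10), and ENSAOCG00000003252 in library 7 (11.19). ENSAOCG00000020520, which T3 raised, was highest in DMSO libraries 9 and 1 (6.74 and 6.64). DMSO libraries 8 and 10 were the furthest of their group along the T3 axis, at 0.201 and 0.242. These genes were singled out after their values were seen.

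DMSO libraries may differ along the genes that T3 changes, a hypothesis that came from these data. It was tested on 5597 genes that rose and 5825 that fell with T3, without the genes named here. Across the 10 DMSO libraries, the place on the axis from genes that rose correlated with the place from genes that fell at r = 0.881 (permutation p = 3e-04, adjusted p = 0.0018 over 6 of the correlations computed; Spearman rho 0.879, p = 0.00148), and at 0.748 without libraries 7 and 10. Normalisation can tie the places together, and permuting the T3 differences among the genes gave r of -0.998 to -0.821, too far below to decide anything. The places were therefore taken again relative to the 11185 genes not called with T3. The correlation was then 0.893 (permutation p = 0.00152, adjusted p = 0.00448; rho 0.782, p = 0.0104), and 0.608 without libraries 7 and 10. Within DMSO libraries 5 to 10 it was 0.944 (n = 6, exact permutation p = 0.0222; rho 0.829, p = 0.0583), and DMSO libraries 1 to 4 were too few. With an axis from T3 and SR9243 libraries alone, which shares no DMSO library with the places, the correlation was 0.627 (permutation p = 0.049, adjusted p = 0.0588; rho 0.648, p = 0.0506), 0.719 without libraries 7 and 9, and 0.743 within DMSO libraries 5 to 10 (n = 6, exact permutation p = 0.0917; rho 0.714, p = 0.136). This test did not pass the correction, so the hypothesis stays open.

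Across the 10 SR9243 libraries the correlation of the same 2 places, not relative to uncalled genes, was 0.851 (permutation p = 0.00224, adjusted p = 0.00448; rho 0.794, p = 0.00954), and 0.51 without libraries 3 and 10. Across the T3 libraries it was 0.345 (permutation p = 0.334; rho 0.467, p = 0.179). The sets of SR9243 and T3 libraries hold 5 libraries each, fewer than the 6 required here, and no correlation was computed within them. No source of such a difference was tested.

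SR9243 and T3 libraries differed from DMSO in the same direction in 4832 genes, and technical sources of this agreement were weighed. Of 100 divisions of the 30 libraries, 1, the real one, reached that count, and the highest other gave 0. Shuffling all labels removes both responses, so this shows that groups differed and cannot decide whether the responses agree. It also treats the libraries as independent, which the labels do not establish. The shared control libraries are argued against as the source, because the covariance kept 92.6% of its value with the DMSO libraries split between the comparisons. The unusual DMSO libraries 4 and 7 are argued against too (90.2% of the covariance without them), and so is an unequal mix of the 2 sets, since the covariance was 0.164 within the second set, whose DMSO libraries scored like its treated ones, and the highest in 100 simulations with 5 libraries per group was 0.0825. A difference common to all DMSO beakers stays open: it would enter both comparisons, and that T3 gave the larger change in 37.6% of shared genes does not decide it, so it cannot be told apart from a shared effect of the treatments.

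Chance division was also tested for the 3 comparisons. In each, 1 of 100 divisions of the 20 libraries, the real one, reached the count of called genes. This argues against a chance division only if the libraries are independent, which the labels do not establish. A difference between beakers that went with the treatment would give the same rank. The highest other division called 2285 genes for SR9243 against DMSO (real 6568), 5049 for T3 against DMSO (real 11430) and 683 for SR9243 against T3 (real 7841).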
